A study of Mus musculus with 4 samples.

How the data were processed

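The 4 groups of male LDLr-/- mice were each represented by 1 pooled sample of aortic RNA from 3 mice, hybridised to 1 array. Per the labels' protocols, 150 ng of total RNA was amplified and labelled with Cy3 on the low input protocol for a single colour. Per the submitters' processing notes, images were quantified with Agilent Feature Extraction 10.7.3.1. The deposited scanner values are intensity on a linear scale, background-subtracted and detrended within each array per the file headers, and not normalized between arrays. Each array held 174979 spots, of which 157716 were not controls, giving 39429 probes with 4 spots each. No spot was saturated, and 2.35% to 2.85% of non-control spots carried an outlier flag and were left out. Median signals were 140, 144, 162 and 152 intensity units in the control and IRI pools at 3 weeks and the control and IRI pools at 10 weeks. The number of arrays, 1 per group, limits the precision.

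The submitters' value table, also intensity as deposited by the authors, is linear and not centred, with every array's 75th percentile at 1500 and a floor of 15, and its column medians are 106, 110, 107 and 120 in that order. For probes with signal over 500 it was within 5% of a constant times the median spot signal in at least 99.8% of probes. Its scale and direction were settled by that match, and how it combines spots is not stated.

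Levels were log2 of the processed signal, averaged over the unflagged spots of a probe, minus the array's 75th percentile over non-control probes. Of 39429 probes, 28328 were named through a RefSeq accession in a table of assembly GRCm38.p6, used for names only, and 1359 of these names differ from the file. Another 11101 kept the file's name. Probe positions are those of the files, on mm9. Each of the 30011 gene names took its brightest probe by the mean over the arrays. Of genes at least 2-fold apart, 23, 54, 66 and 87 had another measured probe in the 4 comparisons (IRI at 3 weeks, IRI at 10 weeks, time in control, time in IRI), and in 2, 9, 9 and 5 of them another probe had the opposite sign, by at least 2-fold in 0, 0, 1 and 0.

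A gene was measured in a comparison if its probe was well above background in most spots on both arrays, and genes at least 2-fold apart were counted. For a gene not above background on one side, a lower bound was taken against the higher of the dim array's lowest signal well above background and the probe's own level. With 1 pool per group no test was made. Before the data were examined, 41 gene lists were fixed, of which 40 had at least 5 measured genes in each comparison. A list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and it was said to stand apart below the 2.5th or above the 97.5th percentile, as a description of these arrays. For lists of randomly drawn genes 2 of the 40 would. Genes of a fixed list can move together, so this rate is no baseline for those lists. There were 27, 17, 25 and 23 lists apart in the 4 comparisons. After values were seen, 9 lists of other tissues were added.

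Named genes followed a rule fixed with the lists. It took the 12 largest and 12 smallest differences in each IRI comparison and the 6 largest and 6 smallest in each time comparison, among genes at least 2-fold apart whose spots on the 2 arrays did not overlap, and left out accession-like symbols. It added the 3 largest lower bounds per direction in the IRI comparisons, up to 4 members of each list that stood apart, 24 fixed genes, and up to 6 genes per direction with opposite effects at 3 and 10 weeks. Genes named from the added lists or from the overlap of the IRI effects fall outside it and were chosen after their values were seen.

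Alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, the submitters' table, no filter or a stricter filter on dim probes, the mean of a gene's probes, the median over spots, either pair of the spots, a floor on low signals, unmatched random lists and lists without genes of other cell types. The calculation was tested on simulated arrays for the comparison of IRI with control at 3 weeks (19259 genes). All 50 genes changed 3-fold, all 50 changed 6-fold and all 50 changed 12-fold were called. None of 50 changed 1.5-fold was called, and 1 unchanged gene was. The changed genes were drawn from genes above background on all 4 arrays and kept that status after the change. The simulation therefore does not show how many genes are missed because they fall to background. A list of 20 genes shifted by 0.3 log2 gave a median of 0.31, and 6.5% of 200 unshifted lists stood apart. Apart from these changes and an offset per array, the simulated arrays varied only by the spread between spots. They held no spread between mice or pools, so they give no rate of false calls between pools. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.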

Results

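Aortic gene expression was measured in male mice without the low-density lipoprotein receptor (LDLr-/-), a strain that develops atherosclerosis on a fat-rich diet. Mice had unilateral kidney ischemia reperfusion (IRI), in which the blood supply of a kidney is stopped and then restored, or control surgery, and then ate a fat-rich diet during 3 or 10 weeks. The 4 groups were control at 3 weeks, IRI at 3 weeks, control at 10 weeks and IRI at 10 weeks. Each was a single pool of aortic RNA from 3 mice on 1 array, so no difference below has a replicate check and no p-value, standard error or test between conditions is given. Levels are log2 signals relative to the array's 75th percentile, and an SD beside a level is the technical spread between the 4 spots of a probe on the same array. It says nothing of the spread between mice. The median spot SD was 0.0631 to 0.0713 log2, and 18895 to 19733 of 30011 genes were well above background on each array. Between a pair of the spots and the remaining pair on the same array, 20 to 27 genes differed at least 2-fold.

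The first comparison asked how the aorta differed after kidney IRI and 3 weeks of diet. Foam cell genes, which mark lipid-loaded macrophages, were higher in the IRI pool. Of 19 measured genes of this list, 9 were at least 2-fold higher and 0 were at least 2-fold lower. The median difference was 0.94 log2, above the range of random lists matched on expression (-0.03 to 0.10). Cd5l, a macrophage-secreted apoptosis inhibitor, was at 3.11 ± 0.02 (spot SD) in the IRI pool and -0.86 ± 0.06 in the control pool, a 15.7-fold difference. Its probe lies on chromosome 3 from 87174823 to 87174882 (mm9). Spp1, which encodes the matrix protein osteopontin, was 5.90-fold higher, the proton pump subunit gene Atp6v0d2 5.15-fold and the elastase gene Mmp12 2.88-fold. The general macrophage list had a median of 0.28 with 0 of 18 members at least 2-fold higher, and Cd68, a lysosomal macrophage marker, was 1.78-fold higher. Cytokine and chemokine genes had a median of 0.51, with 4 of 21 at least 2-fold higher and 1 at least 2-fold lower. Among them the monocyte attractants Ccl3, Ccl4 and Ccl2 were 3.81-fold, 2.09-fold and 2.11-fold higher, and the B cell attractant Cxcl13 was 3.32-fold higher. In the neutrophil list, with a median of 0.25 over 9 genes, Lcn2 was 2.82-fold and S100a9 2.01-fold higher. With normexp background correction Mmp12 (0.70 log2), Ccl4 (0.73) and S100a9 (0.95) were under 2-fold, and Ccl3 was 2.15-fold higher.

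Fat genes were also higher in the IRI pool at 3 weeks. The brown fat list had a median of 0.65 with 4 of 20 genes at least 2-fold higher, the adipocyte list 0.54 with 1 of 21, the lipogenesis list 0.43 with 2 of 18 and the fatty acid oxidation list 0.38 with 0 of 24. Elovl3, a fatty acid elongase of brown fat, was 2.32 log2 higher, Ucp1, the uncoupling protein of brown fat, 2.01-fold, and Fasn, the fatty acid synthase gene, 2.18-fold. Ucp1 was under 2-fold (0.95 log2) with scaling to the array median. These differences stood beside higher foam cell genes in the same pool, and 7 of the 19 foam cell genes are also expressed by fat. Without those 7 the foam cell median was 1.10. Mesothelial and epithelial genes had a median of 1.12, with 5 of 9 at least 2-fold higher, among them Krt8 (2.69-fold), Wt1 (1.32 log2), Lrrn4 (2.26-fold) and Msln (2.25-fold). With normexp Krt8 (0.82 log2), Wt1 (0.82) and Lrrn4 (0.58) were under 2-fold. Skeletal muscle genes had a median of 0.28, with 5 of 14 at least 2-fold higher and Myh4, a fast myosin, 6.77-fold higher. The skeletal muscle list did not stand apart when restricted to genes above background on all 4 arrays. Lists that were lower included cardiac muscle (median -0.24, 0 of 13 at least 2-fold lower), erythroid genes (-0.29, 0 of 7) and immediate early genes (-0.27, 2 of 20). Atf3, a stress-induced transcription factor, was 3.75-fold lower and Btg2 2.15-fold lower. Smooth muscle and endothelial lists did not stand apart, with medians of 0.04 each.

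The genes farthest apart at 3 weeks included genes outside these lists. Svs5 and Svs6, which encode seminal vesicle secretory proteins, were 213-fold and 192-fold higher in the IRI pool. Svs5, with its probe on chromosome 2 from 164159979 to 164160038 (mm9), was at 4.07 ± 0.03 against -3.66 ± 0.22. Sva was 55.2-fold, Spink1 36.5-fold, Bex1 6.16-fold and Slurp1 3.80-fold higher, and the remaining genes of the 12 largest are named above. These 12 are the largest among genes measured in both pools with a usable symbol. Svs4, Svs2 and Svs1 were not well above background in the control pool and were at least 217-fold, 198-fold and 180-fold higher in the IRI pool. With normexp these bounds were 56.4-fold, 46.7-fold and 47.2-fold, and Svs6 was 68.7-fold, Sva 22.9-fold, Spink1 14.6-fold, Bex1 3.20-fold and Slurp1 2.09-fold higher. In the other direction Dbh, the enzyme that makes noradrenaline, was 77.3-fold lower in the IRI pool, at -5.34 ± 0.23 against 0.94 ± 0.01 (chromosome 2 from 27038665 to 27038724). Chgb (10.6-fold lower), Tmem179 (10.2-fold), Sult4a1 (9.02-fold), Ddc (7.57-fold), Gng3 (6.57-fold), Ngfr (6.41-fold), Prph (6.40-fold), Stmn3 (5.45-fold), Th (4.32-fold), Ap3b2 (at -5.51 against -3.51) and Slc6a2 (3.91-fold) followed. Several of these, such as Th and Slc6a2, serve noradrenaline synthesis or uptake in sympathetic neurons. Npy, Syt1 and Scg2 were not well above background in the IRI pool and were at least 47.7-fold, 17.9-fold and 15.8-fold lower there. With normexp these bounds were 14.8-fold, 5.51-fold and 4.88-fold, Dbh was 31.6-fold lower, and Tmem179 (5.01-fold), Sult4a1 (4.13-fold), Prph (4.10-fold), Gng3 (2.71-fold) and Ap3b2 (2.02-fold) were also less far apart. Of 19258 genes measured in both pools, 110 were at least 2-fold higher and 66 at least 2-fold lower, and 96.6% differed less than 1.5-fold. Among genes above background in a single pool, 35 were at least 2-fold higher and 52 at least 2-fold lower by their lower bound. With normexp background correction the counts were 59 and 38, and with no filter on dim probes 388 and 270.

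**Figure D1:**
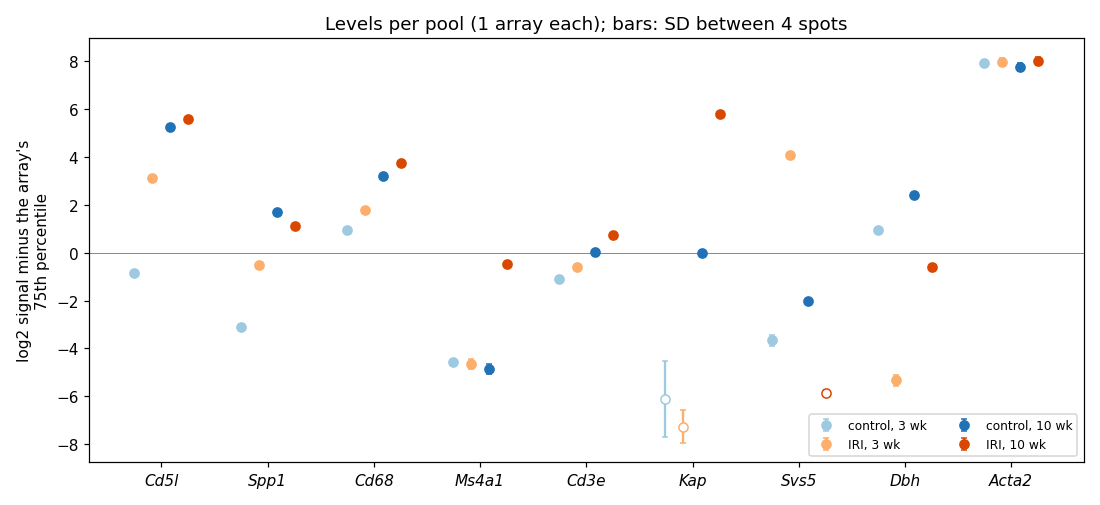
Level of 9 genes in each pool, as log2 signal minus the array's 75th percentile, with bars for the SD between the spots of the array and open symbols for probes not well above background. Kap reached 5.81 in the IRI pool at 10 weeks, Svs5 4.07 in the IRI pool at 3 weeks, and Acta2, a smooth muscle actin gene, lay between 7.76 and 8.01 in all pools.

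The second comparison asked the same after 10 weeks. B cell genes were higher in the IRI pool, with a median of 3.41 and 8 of 10 measured members at least 2-fold higher. Ms4a1, which encodes the B cell surface protein CD20, was at -0.46 ± 0.01 against -4.87 ± 0.21, 21.2-fold higher, with its probe on chromosome 19 from 11325367 to 11325426 (mm9). Fcmr, an immunoglobulin M receptor gene, was 23.5-fold higher, Spib 12.9-fold and Cr2, a complement receptor gene, 12.8-fold. With normexp Ms4a1 was 12.4-fold, Fcmr 9.49-fold and Spib 6.43-fold higher. T cell genes had a median of 1.58, with 12 of 17 at least 2-fold higher, among them Ccr7 (3.69-fold), Cd3d (3.52-fold), Cd2 (3.38-fold) and Tcf7 (3.38-fold). MHC class II genes, which serve antigen presentation, had a median of 0.73, with H2-Oa 4.30-fold (2.85-fold with normexp) and H2-Ob 3.05-fold higher (2.28 log2 with the mean of its probes). Cxcl9 and Ccl5, both T cell attractants, were 4.05-fold and 3.05-fold higher, within a cytokine list whose median was 0.20. The foam cell list had a median of 0.31 with 0 of 19 genes at least 2-fold higher, and the macrophage list 0.24 with 0 of 18. Spp1 was 1.47-fold lower in the IRI pool.

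Mesothelial and epithelial genes had a median of 1.81 at 10 weeks, with 4 of 7 at least 2-fold higher. These included Wt1 (7.62-fold, 4.01-fold with normexp) and Krt8 (7.42-fold, nearly the same as Wt1 with normexp). The brown fat list had a median of 0.63, with Ucp1 2.01-fold (0.83 log2 with scaling to the array median), Elovl3 3.11-fold and Slc27a2, which the kidney also expresses, 23.5-fold higher. Adipocyte, lipogenesis and fatty acid oxidation lists had medians of 0.22, 0.32 and 0.20. Cardiac muscle genes had a median of 0.37, with 2 of 13 at least 2-fold higher. That list did not stand apart when levels came from only spots 1 and 2 of each probe. Endothelial adhesion genes (-0.13) and adventitial fibroblast genes (-0.10) were lower by small amounts, and 0 of their 15 and 16 measured members were at least 2-fold lower. Quantile normalization, the median over spots and the use of only spots 1 and 2 each ended the call for endothelial adhesion, and random lists not matched on expression ended it for fibroblasts.

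The 12 genes farthest above at 10 weeks were taken among genes measured in both pools with a usable symbol. A transcript without such a symbol was higher still, by 7.43 log2. Of the 12, Lrp2, Kap, Acsm2 and Hnf4a belong to a proximal tubule list written after these values were seen. Mep1a, a protease gene of the proximal tubule brush border, was 79.9-fold higher in the IRI pool, at 1.67 ± 0.06 against -4.65 ± 0.24 (chromosome 17 from 43611284 to 43611343). Egfbp2 (77.8-fold), Klk1b5 (75.2-fold), Akr1c21 (68.1-fold), Lrp2 (63.4-fold), Cyp2a4 (62.2-fold), Klk1b26 (61.5-fold), Hsd3b4 (58.5-fold), Kap (55.8-fold), Acsm2 (55.4-fold), Hnf4a (47.2-fold) and Guca2b (46.5-fold) completed the 12 largest. Lrp2 encodes megalin, the endocytic receptor of the proximal tubule, and Kap a kidney androgen-regulated protein. In that list all 14 measured genes were higher, with a median of 4.56. These kidney genes and the lymphocyte genes were high in the same pool. Pth, the parathyroid hormone gene, was at least 860-fold higher, Umod, which encodes the urinary protein uromodulin, at least 279-fold and Slc17a1 at least 103-fold. With normexp these bounds were 217-fold, 74.4-fold and 26.0-fold, and 11 of the 12 largest, all but Kap, lay between 19.3-fold (Hnf4a) and 45.2-fold (Mep1a). Lower in the IRI pool were Nefl (10.9-fold), Syt1 (8.92-fold), Bex2 (8.76-fold), Rit2 (8.71-fold), Vstm2l (8.26-fold), Scg2 (8.03-fold), Dbh (7.89-fold), Npy (7.84-fold), Chgb (7.61-fold), Phox2a (7.28-fold), Phox2b (6.81-fold) and Tmem130 (6.69-fold). Phox2a and Phox2b specify autonomic neurons. Svs5 was at least 13.7-fold and Htr3a at least 9.65-fold lower, with the bound of Slc7a14 between them. With normexp Nefl (6.50-fold), Vstm2l (5.04-fold), Rit2 (4.96-fold), Phox2b (3.46-fold), Tmem130 (3.45-fold) and the bounds of Svs5 (4.80-fold), Htr3a (3.97-fold) and Slc7a14 (3.73-fold) were closer. By such bounds 246 more genes were at least 2-fold higher and 60 at least 2-fold lower. Of 18618 measured genes, 402 were at least 2-fold higher and 118 at least 2-fold lower, so 77.3% of these were higher. Scaling to the array median gave 291 and 161, or 64.4% higher, and moved the median of all genes from 0.01 to -0.17. Without the genes of the kidney and other lists written after the values were seen, the lymphocyte lists and the fat lists, 359 and 104 were left.

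**Figure D2:**
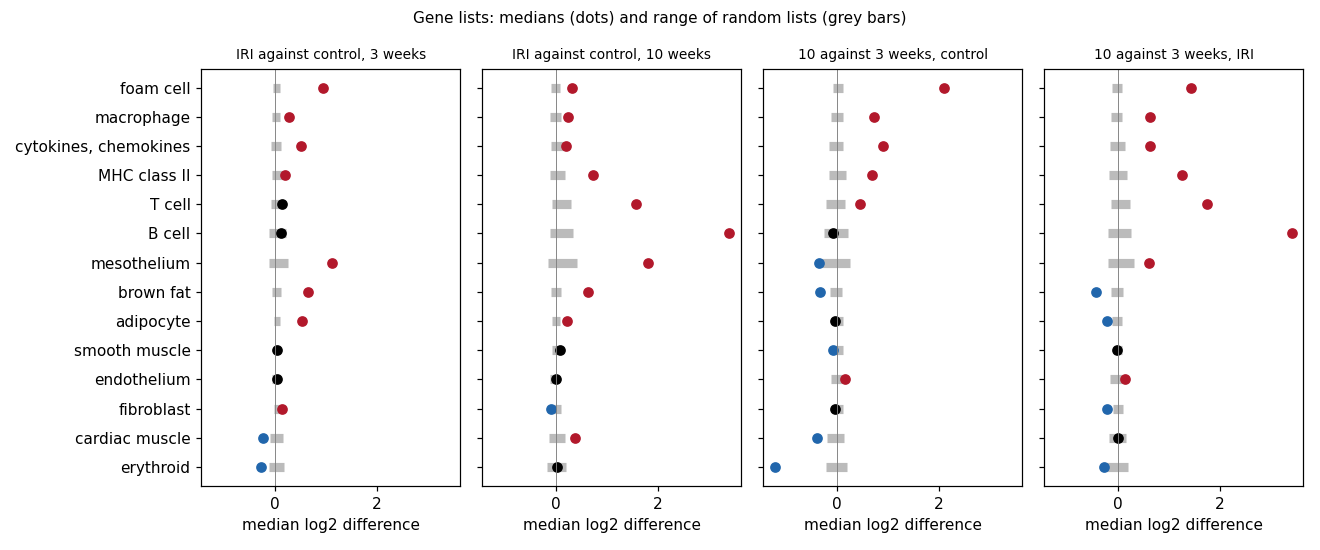
Median log2 difference of 14 gene lists in each of the 4 comparisons, on a shared axis, with red dots for lists that stood apart as higher, blue as lower and black for neither, and grey bars for the range of random lists. The B cell median was 0.12 at 3 weeks and 3.41 at 10 weeks for IRI against control, and the foam cell median 0.94 and 0.31.

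Time on the diet was compared within each surgery. Every array was also used in an IRI comparison, so a level particular to a pool appears in both. The time results are therefore not separate evidence. Time on the diet also went together with time since surgery and could not be told apart from it. In control pools the foam cell list had a median of 2.10 between 10 and 3 weeks, with 12 of 19 genes at least 2-fold higher. Cd5l was 69.3-fold, Spp1 27.4-fold, Atp6v0d2 22.6-fold and Mmp12 3.42 log2 higher at 10 weeks. Bex1 was 40.9-fold, Ccl3 16.0-fold and Lcn2 10.9-fold higher. Macrophage genes had a median of 0.72 (7 of 18 at least 2-fold higher), cytokines and chemokines 0.90 (10 of 21), MHC class II genes 0.70 (1 of 10), T cell genes 0.45 (2 of 16) and cell cycle genes 0.34 (0 of 27). Vcam1 and Sele, endothelial adhesion genes, were 2.66-fold and 2.72-fold higher, and the cartilage collagen gene Col2a1 5.02-fold higher. With normexp Bex1 was 18.0-fold, Ccl3 6.90-fold and Col2a1 2.06-fold higher, Mmp12 was less far apart, and Sele was under 2-fold (0.62 log2). Lower at 10 weeks were erythroid genes (median -1.23, 4 of 7), cardiac muscle genes (-0.40, 3 of 13), immediate early genes (-0.37, 2 of 20), brown fat genes (-0.34, 0 of 20) and smooth muscle genes (-0.09, 0 of 19). Myh4 and Nppc, not well above background at 10 weeks, were at least 7.11-fold and 3.88-fold lower there (2.44-fold and 1.79-fold with normexp). Among genes with a usable symbol measured in both pools, the 6 farthest below were Anp32a (5.30-fold), Nppa (4.58-fold), Mb (4.03-fold), Bpifa1 (3.87-fold), Myl3 (3.76-fold) and Ckmt2 (3.76-fold). Of these, Nppa, Mb, Myl3 and Ckmt2 are heart or striated muscle genes. Anp32a was at -1.40 log2 with the mean of its probes and Bpifa1 2.11-fold lower with normexp. Of 19282 measured genes, 379 were at least 2-fold higher and 80 at least 2-fold lower. With normexp background correction the counts were 242 and 35.

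In IRI pools the foam cell median was 1.44 between 10 and 3 weeks, with 10 of 19 genes at least 2-fold higher, and the macrophage median 0.64 with 6 of 18. Atp6v0d2 was 5.54-fold, Cd5l 5.50-fold and Gpnmb, a lysosomal glycoprotein gene, 5.40-fold higher. B cell genes had a median of 3.42 (9 of 11), T cell genes 1.75 (14 of 16), MHC class II genes 1.25 (6 of 10) and cytokines and chemokines 0.63 (7 of 21). Fatty acid oxidation (-0.38, 0 of 24), brown fat (-0.43, 0 of 20 lower and 1 higher), lipogenesis (-0.26, 0 of 18) and extracellular matrix (-0.17, 0 of 29) lists were lower. Kap, Pth and Aldob, not well above background at 3 weeks, were at least 4122-fold, 717-fold and 508-fold higher at 10 weeks. With normexp these bounds were 1031-fold, 189-fold and 129-fold. Among genes with a usable symbol measured in both pools, Miox (95.9-fold), Chga (88.6-fold), Lrp2 (51.6-fold), Pdzk1 (49.2-fold), Ugt3a2 (30.6-fold) and Slc22a6 (28.7-fold) were farthest above. With normexp they were 52.1-fold, 49.9-fold, 18.9-fold, 18.1-fold, 14.2-fold and 14.5-fold higher. Miox, Lrp2, Pdzk1 and Slc22a6 are expressed in the proximal tubule. Svs5, Svs6 and Svs4, not well above background at 10 weeks, were at least 945-fold, 210-fold and 153-fold lower there. With normexp these bounds were 295-fold, 64.2-fold and 47.6-fold. Among genes with a usable symbol measured in both pools, Dbp (4.58-fold), Cirbp (3.23-fold), Ap2b1 (2.82-fold), Nr1d1 (2.76-fold), Hbb-b1 (2.67-fold) and N6amt1 (2.66-fold) were farthest below. Of these, Dbp and Nr1d1 are circadian clock genes. The clock list as a whole did not stand apart, with a median of -0.08 and 8 of 16 genes above 0. A median can stay near 0 when members move in opposite directions. It therefore cannot tell whether clock genes differed between these pools, and the time of day at harvest was not examined. With the mean of their probes N6amt1 (-0.86 log2) was under 2-fold and Cirbp was at -1.02 log2. By lower bounds 280 genes were at least 2-fold higher and 38 at least 2-fold lower. Of 18543 measured genes, 545 were at least 2-fold higher and 36 at least 2-fold lower. The lower count was 18 with normexp, 65 with quantile normalization and 68 with scaling to the array median, which moved the median of all genes from -0.02 to -0.14.

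The IRI effects at 3 and 10 weeks shared no array. Across the 18414 genes measured on all 4 arrays, which are not independent replicates, they correlated with Pearson r = 0.338 and Spearman rho = 0.375. The 21 genes at least 2-fold higher at both times (1.85 expected if the effects were independent) included the brown fat genes Ucp1 and Elovl3. They also included Spink1, the genes Wt1, Krt8 and Msln of the mesothelial and epithelial list, and the skeletal muscle genes Tnni2, Pvalb, Myh8 and Cacna1s. Slc27a2, in the brown fat list but also expressed by the kidney, was 1.09 log2 higher at 3 weeks and 4.55 at 10 weeks. With normexp 11 genes were higher at both times, and with no filter on dim probes 60. Pvalb (0.94 log2), Wt1 (0.82) and Krt8 (0.82) were under 2-fold at 3 weeks with normexp. The 36 genes at least 2-fold lower at both times (0.306 expected) included the neuronal genes Dbh, Th, Ddc, Slc6a2, Prph and Chgb. The expected counts do not allow for genes of the same tissue moving together, so they are no baseline for a repeated IRI effect. In 9 genes the effects were opposite, all lower at 3 weeks and higher at 10 weeks. Chga, a secretory granule protein gene, was the only one of them with a usable symbol. The effect was at least 2-fold higher at 10 than at 3 weeks in 348 genes and at least 2-fold lower in 96. With normexp the lower count was 49, and with no filter on dim probes the counts were 1504 and 505.

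**Figure D3:**
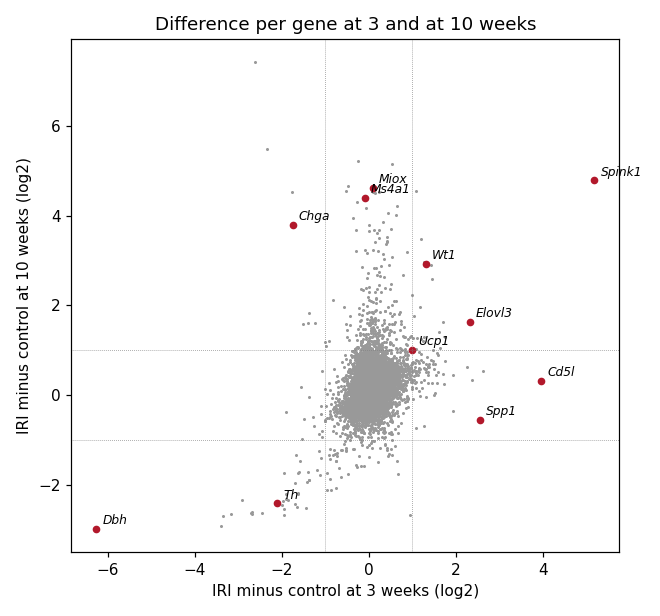
Difference between the IRI and control pools at 3 weeks (horizontal axis, log2) and 10 weeks (vertical axis, log2), with a point for each gene measured on all 4 arrays and dotted lines at 2-fold. Dbh lay at -6.27 and -2.98, Cd5l at 3.97 and 0.31, and Chga at -1.75 and 3.80.

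The 24 fixed genes were read on all 4 arrays. Ldlr, the gene targeted in this strain, was at -3.64, -3.95, -4.38 and -4.11 in the control and IRI pools at 3 weeks and the control and IRI pools at 10 weeks. The deleted part relative to the probe was not known, so this checks nothing about the genotype. The smooth muscle gene Myh11 was at 4.86, 4.85, 4.57 and 4.90, and Cd68 at 0.95, 1.78, 3.20 and 3.73, in the same order. Vcam1 was at 2.24, 2.55, 3.65 and 3.38, Ccl2 at -1.39, -0.32, 0.43 and 0.59, and Cd79a, a B cell receptor component, at -4.22, -3.89, -4.04 and -0.88. Il6 was at -4.93, -4.24, -3.84 and -3.33 and Il1b at -4.53, -4.03, -4.03 and -3.59. Tnf lacked a level above background in at least 1 pool of every comparison, and Runx2 was not above background in any pool.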

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

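Tests of kidney tissue, lymph node tissue, lymphocytes, smooth muscle share and lesion stage were chosen after the results were seen, and those of array scaling and periaortic fat before their own results were seen. The ranges given with these tests come from resampling the member genes of the lists within the same arrays. Genes of a list can move together, so the ranges describe these arrays and give no spread between mice or pools. What is argued against below is therefore argued for these pools only. Chga differed in opposite directions, by -1.75 log2 at 3 weeks and 3.80 at 10 weeks for IRI minus control, and the difference was not tested. The adventitial fibroblast list stood apart in opposite directions, at 0.13 at 3 weeks and -0.10 at 10 weeks, and the difference was not tested. The cardiac muscle list also did so, at -0.24 at 3 weeks and 0.37 at 10 weeks, and the difference was not tested.

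Kidney tubule genes were higher in the IRI than in the control pool at 10 weeks. Array scaling alone is argued against by size. The 4 scaling and background alternatives left the median of all genes between -0.17 and 0.03. The proximal tubule median stayed between 4.04 and 4.55, and shifts that small could hardly have given another outcome. That list was also written after these values were seen. Kidney tissue in the pool may be the source: 16 genes of other kidney segments above background in the IRI pool had a median difference of 2.11 (resampling range 0.22 to 3.21), and 11 of them were at least 2-fold higher. That choice of genes favours a high median. The 8 measured in both pools had a median of 0.18, with Cdh16 at 3.21, Clcnkb at 2.86 and Fxyd2 at 2.34. The other members of the 8 lay between -0.03 (Nphs1) and 0.22 (Pax2). This second choice favours a low median, because it leaves out members not above background in the control pool. Among those left out, levels in the IRI pool were Egf -1.15, Kcnj1 -1.85, Kl -2.57, Slc12a1 -3.28, Pax8 -4.59, Aqp3 -4.73 and Calb1 -5.03. In the IRI pool Kap was at 5.81, Fxyd2 at 3.11 and Aldob at 2.78, and 8 of 17 proximal tubule and 9 of 21 other kidney genes were above background in the control pool at 3 weeks too. Whether IRI itself contributed was not tested.

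B cell and T cell genes were higher in the IRI than in the control pool at 10 weeks. A lower share of smooth muscle is argued against as the whole cause, since it would raise endothelial genes alike, and the B cell median exceeded the endothelial median by 3.41 (resampling range 1.03 to 4.02). Lymph node tissue in the pool cannot be told apart from other sources, because 6 stroma and venule genes had a median of 0.48 (range 0.13 to 1.14), between the sizes set for either answer; all 6 were above background in the control pool as well, 3 are in the fixed lists, and the differences were Chst4 1.64, Madcam1 0.64, Glycam1 0.62, Fut7 0.34, Cxcl13 0.25 and Ccl19 0.01, with Ccl19 at a level of 1.49 in the control pool. More lymphocytes in the aortic wall after IRI also stays open, as 1 pool per group cannot separate them from lymphoid tissue beside the aorta. At 3 weeks the B cell median was 0.12.

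Foam cell genes were higher in the IRI than in the control pool at 3 weeks. A lower share of smooth muscle is argued against as the whole cause, as the foam cell median exceeded the endothelial median by 0.90 (resampling range 0.36 to 1.12). More periaortic fat could not be excluded, because the foam cell median without genes that fat expresses was 1.10, with a range of 0.49 to 1.94 that includes the adipocyte median of 0.54. A difference in lesion stage between mice unrelated to IRI cannot be told apart from an effect of IRI with 1 pool per group, and the foam cell median at 10 weeks was 0.31. An effect of IRI on lesion macrophages stays among the open explanations, untested.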

How the results depend on the processing

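The counts without genes of the added lists and the foam cell list without fat-expressed genes were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each group is 1 pool and all carry replicate number 1. All 4 arrays lay on 1 slide with 1 scan, so neither could be fitted, and no library could be left out. A count within 1.5 times, a gene or bound within the combined spot SD of its 2 arrays or a correlation within 0.05 was taken as the same. Of 199 alternative values of counts 22 moved further, of 5201 for named genes 461 and of 192 lower bounds 54, and none of the 195 named-gene differences of at least 2-fold changed sign. Normexp moved all 24 bounds and 183 of 476 named-gene differences, and median scaling 179. By more than 1.5 times, normexp moved 24 bounds and 60 named-gene differences, each to a smaller one, and it brought 2 bounds and 23 called differences under 2-fold. Spots 1 and 2 alone moved 5 bounds and spots 3 and 4 alone 2 by as much, of which 1 was smaller, so the bounds depend on these choices. Of 2014 list values, 58 lost the call and 22 gained one, none with a call in the other direction. Under scaling to the median, 4 lists that stood apart had a median of the opposite sign: NF-kB feedback (-0.04 from 0.14), oxidative stress (-0.06 from 0.12) and glucocorticoid target genes (-0.07 from 0.11) for IRI at 10 weeks, and mineralization genes (-0.01 from 0.11) for time in IRI pools.

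With no filter on dim probes, genes 2-fold higher and lower numbered 388 and 270 for IRI at 3 weeks, 1173 and 324 for IRI at 10 weeks, 732 and 319 for time in control pools and 1269 and 225 for time in IRI pools. Genes were 60 higher at both times, 123 lower at both times and 28 opposite, 1504 had a higher and 505 a lower effect at 10 weeks, and r was 0.216. These counts include probes at background by construction. With normexp they were 59 and 38 for IRI at 3 weeks, 242 and 35 for time in control pools and 18 lower for time in IRI pools, with 11 higher at both times and 49 with a lower effect at 10 weeks. Quantile normalization gave 65 and median scaling 68 lower for time in IRI pools. For normexp and the scalings the cause was not tested. Signal near background limits the rest: 34.2% to 37.0% of genes had no level above it.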

Other observations

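The lists of other tissues described here were written after values were seen. Sympathetic neuron genes were lower in the IRI than in the control pool at both times, with medians of -1.47 over 14 genes at 3 weeks and -2.23 over 18 genes at 10 weeks. Of these, 8 and 13 were at least 2-fold lower. Snap25 was higher in the IRI pool at both times, by 0.18 and 0.43, and Chga, also of this list, was lower at 3 weeks and higher by 3.80 at 10 weeks. Between control pools the same list was higher at 10 weeks, with a median of 1.15 and all 19 genes above 0. Seminal vesicle genes were high in the IRI pool at 3 weeks, where 10 of 10 were above background, against 4, 7 and 1 in the control pool at 3 weeks and the control and IRI pools at 10 weeks. The 4 measured in both pools at 3 weeks had a median of 6.69. Spink1, counted in this list, was not specific to that pool, at -0.23 there and 1.40 in the IRI pool at 10 weeks, where it was 27.7-fold above the control pool. Kidney genes were not limited to the IRI pool at 10 weeks: Kap was at 0.01 in the control pool at 10 weeks and not above background in the control pool at 3 weeks, where its spot SD was 1.59. The lower bound between them was 69.1-fold, with 116-fold from spots 1 and 2, 34.3-fold from spots 3 and 4 and 17.9-fold with normexp. Of 9 adrenal cortex genes, 3 or 4 were above background in each pool.

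Pth was at 3.28 in the IRI pool at 10 weeks and not above background elsewhere. In that pool Chga was at 2.10, the calcium-sensing receptor gene Casr at -5.40, above background there and in no other pool, and Gcm2, a parathyroid transcription factor, at -4.69 against -4.83 in the control pool. Thyroglobulin (Tg) was at -3.66 against -4.13.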
